A study of Mus musculus with 10 samples.

How the data were processed

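ATAC-seq peak lists of 10 samples were analysed, 1 list per sample: 4 single libraries of the first set (ILC2 PBS, ILC2 HDM, CD4 T PBS, Th2 HDM) and 3 WT and 3 Id1tg libraries of ILC2s after HDM. ILC2s were sorted as lineage-negative lung leukocytes positive for CD127, where the lineage cocktail held CD3, CD5 or TCRβ, CD11b, CD11c, CD19, NK1.1 and TCRγδ, and CD4 T cells as TCRβ-positive and CD4-positive. The first set was sorted on another instrument than the second and purified by gel extraction after transposition, so no difference between the sets was tested. Where lists of both sets are given side by side, the values are descriptive. Region sets of the first were read in lists of the second. Per the labels, the authors aligned reads with BWA to mm10 and called peaks with MACS2, with no version or setting stated. In the deposited lists the score column holds 10 times the -log10 q of the peak as a whole number. The deposited fold column is a ratio, the enrichment at the peak summit over the local background of the same library as estimated by the authors. Further deposited columns hold the -log10 p and the -log10 q of each peak against that background, with a lowest -log10 q just above 2 in every list, and the distance of the summit from the peak start. No read counts are part of these lists, so values are called or not called, the depth is unknown, and no value corrects for it.

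Peaks on chromosomes 1 to 19, X and Y were kept. No further filter for repeated or poorly mappable sequence was applied, so peaks at such sites can remain. Each list also held 3 to 7 peaks on the mitochondrial chromosome and 46 to 136 on unplaced contigs, which were left out. Overlapping peaks of a list would have been merged, but none overlapped. For each comparison the peaks of its lists were merged into regions where they overlapped by at least 1 bp, and a region counted as called in a list with a peak overlapping it. Regions were given to the nearest of 21887 protein-coding genes of the GRCm38.p6 annotation (the mm10 build) within 100 kb, measured to the gene body and not to the transcription start site as planned, because the gene table used gives no strand. The motif searches planned (2 results) were not run, since they need the genome sequence.

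WT and Id1tg were compared by peaks, covered length and shares per list with two-sided exact permutation tests (20 assignments, smallest p 0.1), by regions called in all 3 lists of a genotype and none of the other, and by regions per gene. For the last, log2 of called regions plus 0.5 over all called regions of the list was fitted with limma (trend and empirical Bayes) for genes with a mean of at least 1 region, with Benjamini-Hochberg adjustment and a threshold of 0.05. These are not read counts, so no count model was used. The 22 gene lists (type 2 effectors, ILC2 identity, T cell identity, T lineage development, naive T cells, regulatory T cells, E and Id proteins, AP-1 and C/EBP factors, NF-kappaB signalling, STAT5 and cytokine response, antigen presentation and costimulation, inhibitory receptors, migration and residency, ILC1 and NK cells, ILC3 and Th17 cells, B cells, myeloid cells, mast cells with basophils and eosinophils, epithelium, endothelium and stroma, housekeeping, cell cycle) were written before the data were examined, as were the comparisons, tests, alternatives and rule for named genes, except where an alternative is described as added. Lists with at least 5 genes tested (21) were tested with limma camera, two-sided, at a preset correlation of 0.01 and with an estimated correlation. Same-numbered WT and Id1tg samples were not treated as pairs, because the labels do not say what a number marks and their values correlated no better than others (r -0.01, -0.01 and 0.03 across genes). A replicate block was run as an alternative, with an exact sign-flip test (smallest p 0.25) for single values.

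Nothing in the labels says that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. Shares of region sets of the first set in each list were compared by the same exact permutation test, with adjustment over the 8 sets. The plan held 6 of these sets, and the 2 from Th2 HDM and CD4 T PBS were added later. Single libraries were compared without a test, by peaks overlapping by at least 1 bp, by regions per gene, and by the percentile of each gene list's median log2 ratio (A over B, pseudocount 0.5) among 10000 random lists matched on number of regions. The percentile of the mean was not in the plan; it was added because medians often sat on a tied value, and it is named as the mean wherever it is given. Shares of peaks of a single library carry 95% Wilson intervals, which cover counting error only.

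Genes were named by a fixed rule. Id1 and Lck always came first. For WT against Id1tg the rule took up to 10 genes per direction of smallest adjusted p, leaving out any whose direction turned with lists of equal length (genes with too few regions to be tested there, 6 of the 20, stayed in), up to 4 members of smallest p from each list that passed, and up to 4 members with the largest difference from the type 2 effector, ILC2 identity, T cell identity, E and Id protein and AP-1 and C/EBP lists. For single libraries it took 6 genes per direction with the most regions of 1 library only and 3 regions of highest fold enrichment, and for regions specific to a genotype the 4 of highest minimum fold enrichment. Ties were broken by alphabet, so genes tied with the last gene named can be missing.

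Alternatives were lists shortened to the length of the shortest list compared by the authors' -log10 p, a -log10 q of at least 5, regions as 500 bp windows at summits, 50% of the region covered or 50% reciprocal overlap, assignment to all genes whose body plus 5 kb held the region or within 20 kb, a pseudocount of 1, a minimum mean of 2 regions or none, no division by all called regions, the replicate block, each sample left out in turn, and, for region sets, division by the share of all regions of the first set called in the list. Those added after seeing the data were equal length with each sample left out (genotype regions and region sets), summit windows for genes and lists, equal length with an estimated correlation, and, for gene lists, the other gene assignments, pseudocount and filters, and the division for regions of 2 lists of the first set together. The code was checked on small constructed inputs and tested on simulated data, in which list length varied as here and 195 of 11516 genes were changed. Of 49 calls 8 were false, and 7 of 67 genes changed by 1.5-fold, 16 of 65 changed by 2-fold and 18 of 63 changed by 3-fold were recovered, each in the right direction. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.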

Results

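Open chromatin was profiled by ATAC-seq, which marks accessible DNA by transposase insertion, in lymphocytes sorted from mouse lung. Mice had received house dust mite extract (HDM), an allergen that causes type 2 airway inflammation, or saline (PBS) intranasally every 7 days for 3 weeks, and lungs were collected 3 days after the last dose. The 10 peak lists fell into 6 groups. The first set held 1 library each of group 2 innate lymphoid cells (ILC2s) after PBS, ILC2s after HDM, CD4 T cells after PBS and Th2 cells (Foxp3-negative CD4 T cells positive for Gata3 or ST2) after HDM. The second set held 3 libraries of ILC2s from wild-type littermates (WT) and 3 from Id1 transgenic mice (Id1tg), all after HDM. Id1 binds E proteins and blocks their binding to DNA, and the transgene is driven by the proximal promoter of Lck, a kinase gene of lymphocytes. The groups of the first set had no replicates.

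The lists of the first set held 13295 (ILC2 PBS), 11674 (ILC2 HDM), 10179 (CD4 T PBS) and 8953 (Th2 HDM) peaks on chromosomes 1 to 19, X and Y. Lists of the second set were longer, with 38563, 47668 and 37566 peaks in WT 1 to 3 and 40303, 28361 and 25987 in Id1tg 1 to 3. The mean was 41266 ± 5567 (SD, n = 3) in WT and 31550 ± 7672 in Id1tg (two-sided exact permutation p = 0.3, the smallest possible being 0.1). Peaks covered 23.0 ± 4.30 Mb in WT and 20.8 ± 5.88 Mb in Id1tg (n = 3 each, exact permutation p = 0.8). WT 2 stood apart with the most peaks and the narrowest, with a median width of 295 bp against 552 to 587 bp in the other 5 lists of that set. A share of 59.3% ± 0.191 of WT peak summits and 57.2% ± 0.606 of Id1tg summits lay in protein-coding gene bodies (SD, n = 3, exact permutation p = 0.1). Summits within 1 kb of either end of a gene made up 27.9% ± 1.00 and 32.7% ± 5.10 (n = 3, exact permutation p = 0.3). Chromosome Y held 10.7 ± 2.52 peaks in WT and 4.00 ± 4.36 in Id1tg (n = 3, exact permutation p = 0.2). None of them lay within 5 kb of Kdm5d, Eif2s3y, Uty or Ddx3y, the genes checked there. Read counts are not part of the lists, so the sequencing depth behind each list is unknown.

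**Figure D1:**
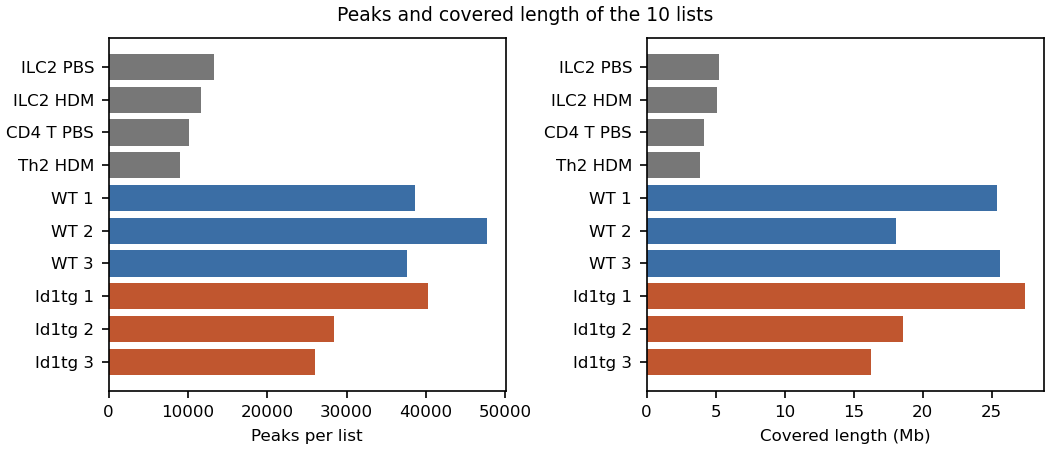
Peaks per list (left, count) and genome length covered by peaks (right, Mb) for each of the 10 lists; grey bars are the 4 single libraries of the first set, blue bars WT and orange bars Id1tg ILC2s after HDM. Lists of the second set hold 25987 to 47668 peaks, each more than any list of the first set.

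The Id1 locus (mm10, chromosome 2, 152736251 to 152737410), which encodes the inhibitor carried by the transgene, had 0 peaks within 5 kb in each of the 4 lists of the first set. It had 2, 2 and 1 peaks in WT 1 to 3 and 2, 1 and 1 in Id1tg 1 to 3. Lck (chromosome 4, 129548344 to 129573641) had 1 peak in ILC2 PBS, ILC2 HDM and CD4 T PBS, 0 in Th2 HDM, 3, 3 and 4 in WT and 3, 4 and 2 in Id1tg. Reads of the transgene can align to both loci, so peaks there in Id1tg cannot be assigned to the endogenous genes.

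The comparison of ILC2 HDM with ILC2 PBS asked which sites opened or closed in these cells with allergen. The PBS list was the longer, which raises its region counts in general. Nfkb1, which encodes a subunit of the inflammatory transcription factor NF-kappaB, had 6 called regions after HDM and 12 after PBS. Icos, a costimulatory receptor that maintains ILC2s, had 0 and 5, and Arg1, an arginine-metabolising enzyme of ILC2s, had 1 and 3. Il1rl1, which encodes the IL-33 receptor ST2, had 2 and 4. Klrg1, a marker of mature ILC2s, had 2 regions after HDM and 0 after PBS. Among cytokine genes, Csf2 (GM-CSF) and Il6 had 1 region after HDM and 0 after PBS, Ccl1 had 2 and 3, and Il9 had 1 and 2.

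By list, antigen presentation and costimulation genes had 17 regions after HDM and 33 after PBS, with 8 of the 17 that had a region higher after PBS and 1 after HDM. The planned statistic, the median log2 ratio, was 0.18 and lay at percentile 49.0 of 10000 random gene lists matched on region number, while the mean, read in addition, was -0.66 and lay at percentile 0. NF-kappaB signalling genes had 39 and 57 regions (median 0.18 at percentile 49.7, mean -0.19 at percentile 2.75), and 9 of the 19 with a region had more after PBS against 1 after HDM. ILC2 identity genes had 46 and 61 regions (median at percentile 2.45, and at 50.6 with assignment by gene body). AP-1 and C/EBP factors had 52 and 51 regions, and their median, the same tied value of 0.18, lay at percentile 98.6, but at 59.5 with lists of equal length. In that list the repressor Bach2 had 11 and 9 regions, the immediate-early genes Fos 4 and 7 and Fosb 5 and 8, and the small Maf factor Mafg 0 and 2. E protein and Id genes had 9 and 12 regions, with Id3 at 0 and 2, Id2 at 4 and 3, Id4 at 1 and 2 and the E protein gene Tcf12 at 1 and 2. Of the T cell identity genes, Cd2 had 0 and 3, Ctla4 0 and 2, Prkcq 1 and 3 and Lef1 6 and 4.

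The genes that gained most regions with HDM were Sfi1 (19 against 13), Btbd35f29 (5 against 1), Adck1 (4 against 1), Basp1 and Capn2 (5 against 2 each) and Cmip (4 against 1). Sfi1 also had more regions in ILC2 PBS than in CD4 T PBS (13 against 6), so its gain cannot be read as particular to HDM. Those with the largest loss, besides Nfkb1 and Icos, were the corepressor gene Bcor (2 against 7), Tnfaip8 (2 against 7), Arhgap15 (1 against 5) and the chromatin remodeller gene Chd7 (5 against 9). Other genes tied with Arhgap15 and Chd7, among them Tnfaip3 (6 against 10). The HDM-only regions of highest fold enrichment lay inside Gtf2ird1 (chromosome 5, 134378903 to 134379101, 6.85-fold), Tatdn1 (chromosome 15, 58927684 to 58927926, 6.53-fold) and Mbnl2 (chromosome 14, 120405064 to 120405537, 6.28-fold). The PBS-only regions of highest enrichment lay 12373 bp from Pigk (chromosome 3, 152701666 to 152701796, 8.35-fold), inside Ccdc62 (chromosome 5, 123930541 to 123930932, 8.30-fold) and 15686 bp from Gtpbp4 (chromosome 13, 9011707 to 9012161, 8.25-fold). Of the HDM peaks, 84.2% overlapped a PBS peak (95% Wilson interval 83.5 to 84.8, counting error only), leaving 1849 HDM-only and 3357 PBS-only peaks. With lists of equal length the numbers were 2256 and 2191, but 2 lists of the same length give nearly equal numbers by construction, here and in the next 3 comparisons.

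Th2 HDM was compared with CD4 T PBS, which differ in both treatment and sorted population. Type 2 effector genes had more called regions in Th2 cells, largely through Il10, and naive T cell and T cell identity genes had fewer. Il10, an anti-inflammatory cytokine also made by Th2 cells, had 4 called regions in Th2 HDM and 0 in CD4 T PBS. The epidermal growth factor family gene Areg and the neuropeptide gene Calca had 1 and 0, and Il2, the growth factor made by naive T cells on activation, had 0 and 1. Bach2, which holds back effector differentiation, had 6 regions in Th2 HDM and 12 in CD4 T PBS. Tcf7 had 0 and 4 and Lef1 4 and 7, both transcription factors of naive and memory T cells, and the costimulatory receptor Cd28 and the T cell receptor kinase Prkcq each had 0 and 3.

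Naive T cell genes had 23 regions in Th2 HDM and 50 in CD4 T PBS, T cell identity genes 14 and 39, and both medians lay at percentile 0 of the random lists. T lineage development genes had 19 and 45 (percentile 0.185), STAT5 and cytokine response genes 16 and 32 (percentile 0.02) and ILC1 and NK cell genes 7 and 18 (percentile 0.005). Type 2 effector genes had 9 and 4 regions (percentile 95.6) and antigen presentation genes 12 and 8 (median at percentile 50.9, mean at 99.5). ILC2 identity genes had 21 and 16 (median at percentile 59.2, mean at 97.7), with Id2 at 3 and 1, Ahr at 2 and 1, Hlf at 2 and 1 and Gfi1 at 1 and 2. E protein and Id genes had 7 and 6, with Id3 at 0 and 1, Tcf12 at 2 and 1 and Tcf4 at 1 and 2. In the AP-1 and C/EBP list, Fosb had 1 and 3 regions, Atf3 2 and 3 and the antioxidant regulator Nfe2l2 4 and 2.

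Genes with the largest gain in Th2 HDM, besides Il10, were Sfi1 (12 against 6), Sv2c (4 against 0) and Adnp2, the cell cycle inhibitor Cdkn2c and Cemip2 (4 against 1 each). Those with the largest loss, besides Bach2, were Adgrl2 (0 against 5) and, at 1 against 6 each, Arid5b, the IL-6 signal transducer Il6st, Mfhas1 and Rras2. The Th2-only regions of highest enrichment lay inside Arhgef28 (chromosome 13, 98124255 to 98124809, 12.4-fold), Chrnb1 (chromosome 11, 69795327 to 69795600, 12.0-fold) and Sfi1 (chromosome 11, 3142560 to 3142746, 11.1-fold). The CD4 T PBS-only regions lay inside Ggt5 (chromosome 10, 75591543 to 75591803, 13.6-fold), Tox, a regulator of T cell development (chromosome 4, 6970497 to 6970832, 13.4-fold), and Pdlim1 (chromosome 19, 40257478 to 40257754, 13.3-fold). There were 1866 Th2-only and 3070 CD4 T-only peaks, and 79.2% (78.3 to 80.0) of Th2 peaks overlapped a CD4 T peak. With lists of equal length the numbers were 2258 and 2256.

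After HDM, ILC2s and Th2 cells were set against each other to find sites that separate the innate from the adaptive type 2 cell. ILC2s had more called regions at genes of ILC2 identity and cytokine response, and Th2 cells at Il10, which had 0 regions in ILC2 HDM and 4 in Th2 HDM. Rora, a nuclear receptor required for ILC2 development, had 7 and 2 regions, Gata3, the master regulator of type 2 lymphocytes, 2 and 0, Lmo4 5 and 1 and the aryl hydrocarbon receptor Ahr 4 and 2. ILC2 identity genes had 46 and 21 regions (percentile 97.3, and 50.0 with lists of equal length) and STAT5 and cytokine response genes 32 and 15 (percentile 99.5). Other type 2 effector genes differed by few regions, with Il2 at 2 and 0 and Ccl5 and Csf2 at 1 and 0. The 0 regions at Il10 rest on the single ILC2 HDM list, and the longer WT lists of ILC2s after HDM held 9, 12 and 9. T cell identity genes had 27 regions in ILC2s and 14 in Th2 cells (percentile 96.1, and 50.5 with lists of equal length), with Cd28 and the Aiolos gene Ikzf3 at 2 and 0, the kinase gene Itk at 4 and 2 and Lef1 at 6 and 4. Among AP-1 factors Bach2 had 11 and 7, Fosb 5 and 1, Atf3 4 and 2 and Batf 2 and 0. Id2 had 4 and 3, Id4 1 and 0, Tcf12 1 and 2 and Tcf4 2 and 1.

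Genes with the most additional regions in ILC2 HDM were Zfp978 (12 against 1), the calcium channel gene Itpr1 (14 against 5), the utrophin gene Utrn (8 against 0), Ldlrad4 (10 against 3), Sfi1 (19 against 12) and Myo16 (6 against 0). Those with the most in Th2 HDM, besides Il10, were Adnp2, Cnot2 and Mmd (1 against 4 each), Gtf2i (2 against 5) and the cytokine receptor gene Il20rb (0 against 3). The ILC2-only regions of highest enrichment lay inside Ndst3 (chromosome 3, 123652922 to 123653411, 8.92-fold) and Edil3 (chromosome 13, 88828248 to 88828745, 8.62-fold) and 34618 bp from 4932411N23Rik (chromosome X, 126777707 to 126777892, 8.34-fold). The Th2-only regions lay 31484 bp from Cnot2 (chromosome 10, 116613253 to 116613489, 11.7-fold), 45 bp from Bcl2a1b, a survival gene of the Bcl2 family (chromosome 9, 89199106 to 89199419, 11.4-fold), and 16707 bp from Ralgps2 (chromosome 1, 156956356 to 156956694, 10.5-fold). ILC2 HDM had 3961 peaks that Th2 HDM lacked and Th2 HDM 1223 that ILC2 HDM lacked, which became 1960 and 1929 with lists of equal length.

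In the PBS-treated lung, ILC2s had 63 regions at ILC2 identity genes against 17 in CD4 T cells (percentile 100), 33 against 8 at antigen presentation genes (percentile 99.8) and 57 against 25 at NF-kappaB genes (percentile 99.9, and 50.1 with lists of equal length). Naive T cell genes went the other way with 29 against 49 (percentile 0.01). Rora had 10 regions in ILC2s and 2 in T cells, Lmo4 7 and 2, Icos 5 and 1 and Il1rl1 4 and 0. The type 2 effector genes Areg, Calca and Ccl5 had 1 and 0 and Ccl1 3 and 2. T cell identity genes had 33 and 39 regions, with Lef1 at 4 and 7, Tcf7 at 2 and 4, Bcl11b, a factor of T cell commitment that ILC2s also use, at 0 and 2, and the kinase gene Zap70 at 3 and 0. Among Id genes, Id2 had 3 and 1, Id4 2 and 0 and Id3 2 and 1, and Tcf12 had 2 and 1. Fosb had 8 and 3, Fos 7 and 3 and Mafg 2 and 0, while Bach2 had 7 and 11.

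Genes with the most additional regions in ILC2 PBS were Zfp978 (11 against 0), Nfkb1 (12 against 2), Synj2 (9 against 0), Itpr1 (12 against 4), Rora, and the transcription factor gene Bhlhe40 (7 against 0). Those with the most in CD4 T PBS were Slc9a9 (2 against 9), Il6st and Rras2 (1 against 6 each), the NF-kappaB regulator Tnip3 (0 against 5), Adgrl2 (1 against 5) and Bach2. The ILC2-only regions of highest enrichment lay inside Jarid2 (chromosome 13, 44869571 to 44870021, 15.0-fold), Edil3 (chromosome 13, 88828295 to 88828678, 11.9-fold) and Sfi1 (chromosome 11, 3142577 to 3142742, 11.7-fold). The Sfi1 region overlaps the one described above as Th2-only, so this site was called in ILC2 PBS and in Th2 HDM and is particular to neither. The T cell-only regions were the region inside Tox described above as absent from Th2 HDM, a region 97387 bp from the corepressor gene Tle4 (chromosome 19, 14695382 to 14695812, 12.5-fold) and a region inside Gtf2i (chromosome 5, 134282463 to 134282904, 12.5-fold). There were 5135 ILC2-only and 2057 T cell-only peaks, and 2722 and 2712 with lists of equal length. In these 4 comparisons, with 1 library on each side, no difference could be tested against replicate spread.

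Of 17217 regions in the 4 lists, 1825 were called in ILC2 HDM and not in ILC2 PBS and 1837 in Th2 HDM and not in CD4 T PBS, which also differ in sorted population. Both held for 247, against 195 if independent among these regions. In the reverse direction the numbers were 3313 for ILC2s and 3030 for T cells. Both held for 466, against 583 if independent among these regions. Regions called in none of the 4 lists are left out of the 17217, so 195 and 583 are not chance values. No excess or lack of sharing can be read from them.

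WT and Id1tg ILC2s after HDM were compared to ask how the E-protein inhibitor changes open chromatin in ILC2s of the inflamed lung. Id1tg ILC2s had fewer called regions at type 2 effector cytokines, antigen presentation and costimulation genes, and relatively more at genes of naive T cells. These are calls on lists of which most members did not pass (11 of 14, 15 of 18 and 10 of 14), and each is lost with an estimated correlation (limma camera adjusted p = 0.313, 0.242 and 0.384 with an estimated correlation). Across the type 2 effector genes, the regions called per list averaged 80.7 ± 13.6 in WT and 40.3 ± 13.7 in Id1tg (SD, n = 3). Il10 (chromosome 1, 131019845 to 131024970) had 9, 12 and 9 regions in WT and 4, 0 and 0 in Id1tg, and Il13 (chromosome 11, 53631323 to 53634702), the type 2 cytokine that drives mucus production, had 5, 5 and 4 against 2, 2 and 1. Dapl1, a gene of naive T cells, went from 2.00 ± 1.00 regions to 7.00 ± 1.00.

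Of 12333 genes tested with limma on regions per gene divided by all regions of the list, 443 had relatively more regions in Id1tg and 484 relatively fewer, with groups apart for 2500 genes (20.3%, where chance gives 10%). With this division the median log2 change of all genes was 0.28, against -0.07 without it, a rise of 0.35, so list changes are given relative to that median. Among the 5388 genes with a mean of at least 2 regions the median was 0.05. Part of a fall relative to all genes can therefore reflect region number. The lists' own medians were -0.57 (type 2 effectors), -0.31 (antigen presentation), -0.12 (STAT5), -0.08 (NF-kappaB) and 0.40 (naive T cells). Without the division 64 genes were higher and 337 lower, and with lists of equal length 368 and 442 of 10988, of which 325 were shared with the 721 earlier calls tested there and 16 had turned. Without Id1tg 1, whose list is the longest of its group, the numbers were 5021 and 894, and without Id1tg 2 they were 262 and 343.

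Type 2 effector genes (14 tested) fell as a list, with a median of -0.84 on the log2 scale relative to all genes and -0.44 with lists of equal length (limma camera adjusted p = 0.000268, and adjusted p = 0.313 with an estimated correlation). The call was lost without the division (camera adjusted p = 0.0996). Leaving the division out lowers every log2 change by 0.35, so the falls themselves did not shrink. Of the 14, 10 had a log2 change below 0 and 4 above, 3 fell, 0 rose and 11 did not pass, and 7 fell when adjusted over the list alone. Il10 fell by 2.97 (limma adjusted p = 0.00161), Il13 by 0.94 (0.0207) and Ccl1, a chemokine that attracts Ccr8-positive cells, by 0.72 (0.0247). Lif, of the IL-6 family, had 9.33 ± 1.53 regions in WT and 4.00 ± 3.00 in Id1tg (n = 3, limma adjusted p = 0.0639), and Csf2 11.7 ± 3.79 and 5.67 ± 3.06 (limma adjusted p = 0.0661). At equal length Il13 and Ccl1 no longer passed (limma adjusted p = 0.112 and 0.399), with log2 changes of -1.09 and -0.21, and Ccl1 and Csf2 turned to higher values when regions were given only to genes whose body plus 5 kb held them.

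Antigen presentation and costimulation genes (18 tested) fell by 0.58 relative to all genes (limma camera adjusted p = 0.000268, and adjusted p = 0.242 with an estimated correlation). Over all genes 3 fell, 0 rose and 15 did not pass, and adjusted over the list alone 5 fell and 1 rose. H2-Eb1, an MHC class II chain (chromosome 17, 34305867 to 34316674), went from 4, 4 and 4 regions to 2, 1 and 1 (limma adjusted p = 0.0102). Cd86, a ligand of Cd28, went from 6, 6 and 6 to 4, 2 and 2 (limma adjusted p = 0.0328), and Tnfsf11, which encodes RANKL, from 12.7 ± 0.577 to 6.33 ± 3.21 (limma adjusted p = 0.0297). The OX40 ligand gene Tnfsf4 had 5.33 ± 1.15 and 2.33 ± 1.53 regions (limma adjusted p = 0.0712).

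STAT5 and cytokine response genes (19 tested) fell as a list, with a median of -0.40 relative to all genes and -0.21 with lists of equal length (limma camera adjusted p = 0.0110, and adjusted p = 0.313 with an estimated correlation). The survival gene Bcl2l1 alone fell over all genes, from 8.00 ± 2.00 to 3.33 ± 0.577 regions (limma adjusted p = 0.0270), 18 did not pass, and 3 fell when adjusted over the list alone. Bcl2 had 19.7 ± 1.53 and 11.7 ± 3.06 regions, Myc 9 ± 1.73 and 4.33 ± 2.52 and the IL-4 receptor gene Il4ra 8.00 ± 1.00 and 4.33 ± 0.577 (limma adjusted p = 0.0543, 0.0610 and 0.145). NF-kappaB signalling genes (19 tested) fell by 0.36 (limma camera adjusted p = 0.0391, and adjusted p = 0.502 with an estimated correlation), with 2 members lower, over all genes and adjusted over the list alone, and 17 not passing. These were the inhibitor gene Nfkbia, from 8.00 ± 2.00 to 3.33 ± 2.31 regions (limma adjusted p = 0.0277), and Nfkb1, from 29.0 ± 3.00 to 17.7 ± 3.79 (0.0298). Birc3 had 6.67 ± 1.15 and 3.67 ± 1.15 regions and the A20 gene Tnfaip3 22.0 ± 4.36 and 14.3 ± 5.13 (limma adjusted p = 0.209 and 0.215). The STAT5 call was lost at equal length (camera adjusted p = 0.0740), with assignment by gene body (0.134), at a mean of at least 2 regions (0.0634) and without Id1tg 3 (0.0747). The NF-kappaB call was lost with the replicate block (camera adjusted p = 0.0908), without the division (0.0996), at a mean of at least 2 regions (0.260) and without WT 1 (0.0755), WT 2 (0.124), WT 3 (0.0567) or Id1tg 3 (0.0974). Myc and Tnfsf4 turned to higher values with the assignment by gene body.

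Naive T cell genes (14 tested) rose by 0.13 relative to all genes (limma camera adjusted p = 0.0423, and adjusted p = 0.384 with an estimated correlation), while the number of regions at these genes was 116 ± 4.93 in WT and 119 ± 37.4 in Id1tg (n = 3). Over all genes and adjusted over the list alone, 4 rose, 0 fell and 10 did not pass. Dapl1 rose by 2.01 on the log2 scale (limma adjusted p = 0.000262), the lymph node homing receptor Sell by 1.38 (0.00927), the chromatin organiser Satb1 by 0.66 (0.0317) and the egress receptor S1pr1 by 0.52 (0.0479). Without the division these changes were 1.66, 1.03, 0.31 and 0.17, and S1pr1 had 16, 13 and 11 regions in WT and 17, 14 and 14 in Id1tg. Sell did not rise at equal length (log2 change -0.02), and the call of the list was lost without Id1tg 1 (camera adjusted p = 0.778), without the division (0.123), with assignment by gene body (0.263) and within 20 kb (0.259).

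ILC2 identity genes (27 tested) had 262 ± 27.4 regions in WT and 190 ± 61.8 in Id1tg and did not pass as a list (limma camera adjusted p = 0.0735, and adjusted p = 0.764 with an estimated correlation), but passed without WT 1 (0.0311) or Id1tg 1 (0.0157), with assignment by gene body (0.0209) or within 20 kb (0.0438) and with a pseudocount of 1 (0.0378). Of the 27, 3 fell, 0 rose and 24 did not pass, and adjusted over the list alone 5 fell and 4 rose. Il1rl1 went from 16, 22 and 19 regions to 17, 7 and 4 (limma adjusted p = 0.0395), Vipr2, a receptor for the neuropeptide VIP that activates ILC2s, from 11.7 ± 1.15 to 5.33 ± 1.53 (0.00884), and Ramp1, the coreceptor of the neuropeptide CGRP, fell by 0.64 (0.0494). Rora had 50.0 ± 6.93 and 32.0 ± 14.2 regions (limma adjusted p = 0.0542) and Pparg, a lipid-sensing receptor of ILC2s, 12.7 ± 1.15 and 7.67 ± 2.08 (0.134). T cell identity genes (26 tested) moved both ways (limma camera adjusted p = 0.860), with 4 higher, 2 lower and 20 not passing, and 7 higher and 3 lower when adjusted over the list alone. Bcl11b (chromosome 12, 107910403 to 108004145) went from 17, 21 and 16 regions to 10, 7 and 4 (limma adjusted p = 0.00168) and the adaptor gene Skap1 from 12.0 ± 1.73 to 5.00 ± 4.36 (0.0213). The 4 that rose were Cd2, Themis, Sh2d1a and Prkcq, and the list's median was 0.15 above 0 and -0.13 relative to all genes. Ikzf3 had 15.0 ± 1.00 and 10.0 ± 3.61 regions and Itk 13.7 ± 2.31 and 9 ± 2.00 (limma adjusted p = 0.292 for both).

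E protein and Id genes (6 tested) did not pass as a list (limma camera adjusted p = 0.839), with a median of -0.13 and a mean of 0.01. Relative to all genes the median was -0.41, and 0.12 with lists of equal length. The E protein gene Tcf4 rose, from 5.67 ± 0.577 to 7.00 ± 1.73 regions (log2 change 0.61, and 0.26 without the division, limma adjusted p = 0.0401), and was the member that passed over all genes and adjusted over the list alone. Id2, which ILC2s require, had 10.0 ± 0.00 and 7.00 ± 1.00 regions (limma adjusted p = 0.531), Id3 5.67 ± 0.577 and 3.00 ± 1.00 (0.15) and Tcf12 5.67 ± 0.577 and 4.00 ± 1.00 (0.668). AP-1 and C/EBP factors (21 tested) did not pass (limma camera adjusted p = 0.445), with 1 lower, and 1 higher and 1 lower when adjusted over the list alone. Batf, an AP-1 factor of type 2 lymphocytes, fell from 8.33 ± 2.31 to 3.67 ± 1.53 regions (limma adjusted p = 0.0443). Bach2 had 26.0 ± 4.00 and 20.0 ± 4.58, Fos 11.7 ± 1.15 and 8.00 ± 2.65 and Jun 6.33 ± 0.577 and 3.67 ± 0.577 (limma adjusted p = 0.819, 0.292 and 0.292).

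Markers of other cells that a sort could hold moved both ways, though endothelial and stromal genes had 4 higher and 1 lower of 10 tested. Over all 12333 genes 443 were higher and 484 lower, a smaller share than in that list or among B cell genes. The list tests cannot exclude such cells in the sorts. Of 8 B cell genes tested, Bank1 and Pou2af1 rose and Ebf1 and Cd22 fell, and of 8 myeloid genes Cybb rose (limma camera adjusted p = 0.860 for each list). Of 7 mast cell, basophil and eosinophil genes, Cma1 and Ccr3 fell, and of 10 endothelial and stromal genes Kdr, Sox17, Erg and Pdgfrb rose and Tbx4 fell (camera adjusted p = 0.839 for each). Of 16 ILC1 and NK cell genes Il18rap fell and of 11 ILC3 and Th17 genes Il17f fell (camera adjusted p = 0.839 and 0.445). Of 4 epithelial genes Hopx fell, too few for a list test. Adjusted over the list alone, the numbers higher and lower were 2 and 2 for B cells, 1 and 0 for myeloid cells, 2 and 2 for mast cells, 4 and 3 for endothelial and stromal cells, 0 and 1 for NK cells, 0 and 2 for ILC3s and 2 and 1 for epithelium. Regulatory T cell genes (9 tested), inhibitory receptors (15), housekeeping genes (15) and cell cycle genes (19) had 0 members past the threshold, over all genes or adjusted over the list alone (limma camera adjusted p = 0.839, 0.445, 0.917 and 0.839). Migration and residency genes (22 tested) had 2 higher, Sell and S1pr1, with the same count adjusted over the list alone (camera adjusted p = 0.691). In several lists the signs differed: the median was above 0 and the mean below for mast cell and ILC3 genes, the reverse held for AP-1 and migration genes, and the test pointed down with a median above 0 for regulatory T, NK, B, housekeeping and cell cycle genes, whose medians lay at -0.17, -0.08, -0.13, -0.17 and 0.07 relative to all genes. Ramp1, the 4 T cell genes that rose and the marker genes of this paragraph were chosen for naming after their values were seen.

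Among the genes with the smallest adjusted p, Slc22a3, an organic cation transporter (chromosome 17), had 0 regions in each WT list and 7, 5 and 4 in Id1tg (limma adjusted p = 2.7e-07). Sucnr1, the succinate receptor, had 0 in WT and 4, 3 and 3 in Id1tg, the calcium-binding protein gene Necab1 0 and 3, 3 and 2, and the olfactory receptor gene Olfr633 0 and 2, 2 and 2. Fstl5 (chromosome 3, 76074275 to 76710010) had 1, 2 and 1 regions in WT and 10, 9 and 9 in Id1tg, Mcc 2.33 ± 0.577 and 9.33 ± 0.577, Stpg2 1.00 and 6.00 ± 1.00, Ccser1 1.00 and 6.33 ± 3.21, the monocarboxylate transporter gene Slc16a7 1.33 ± 0.577 and 7.33 ± 2.52, and the cAMP phosphodiesterase gene Pde4d 14.7 ± 2.52 and 25.3 ± 5.86 (n = 3). In the other direction 9 genes had 0 regions in every Id1tg list. Plekhg1 had 9, 6 and 6 regions in WT, Hmgcll1 5, 6 and 7, Magi1, a junction scaffold, 5, 7 and 4, the kainate receptor gene Grik2 6, 4 and 4, and Wwtr1, which encodes the Hippo pathway coactivator TAZ, 3, 4 and 3. The Rac activator gene Dock1, the splicing factor gene Rbfox3 and D430019H16Rik each had 3, 3 and 4 and Fank1 3, 3 and 3. Trerf1 fell from 18.7 ± 0.577 to 5.33 ± 2.31 regions. The limma adjusted p of these 20 genes was 0.000103 or lower, with no overlap between the 3 WT and 3 Id1tg values. At equal length 13 of the 14 that could be tested kept their call (Stpg2 had limma adjusted p = 0.0918). The rule for naming these genes had left out any that turned at equal length, and of all calls tested there 325 of 721 were kept. Without the division 16 of these 20 kept theirs. Of the 19 called genes named from lists, 7 kept their call at equal length (Il10, Dapl1, Satb1, S1pr1, H2-Eb1, Cd86 and Tcf4), and 1 (Ccl1) without the division. Leaving out the division made falls larger (log2 change -3.32 for Il10 and -1.38 for Bcl11b) and rises smaller (1.66 for Dapl1). With a sample left out, 15, 10 and 13 of the 19 kept their call without WT 1 to 3 and 19, 8 and 16 without Id1tg 1 to 3.

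**Figure D2:**
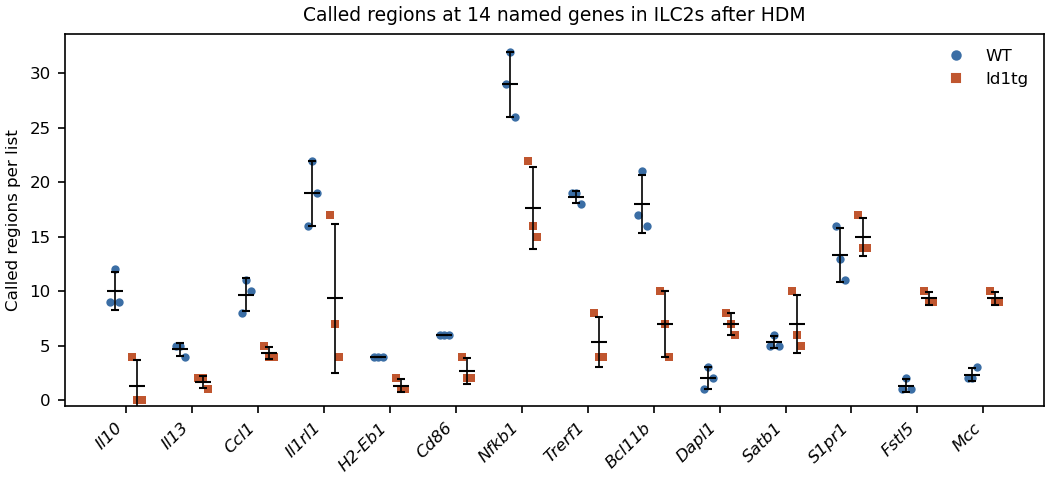
Called regions per list (y axis, count) at 14 named genes in ILC2s after HDM; blue circles are the 3 WT lists, orange squares the 3 Id1tg lists, and black marks the mean and SD. Il10 had 9 to 12 regions in WT and 0 to 4 in Id1tg, and Fstl5 1 or 2 in WT and 9 or 10 in Id1tg.

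Counted by region instead of gene, the 6 lists made 56850 regions, of which 19990 (35.2%) were called in all 6. Of the regions called in either of 2 lists, 70.1 to 75.2% were called in both for 2 WT lists. The share was 59.1 to 73.2% for 2 Id1tg lists and 49.2 to 64.6% for a WT and an Id1tg list. Unequal list length lowers this share, and at equal length the ranges were 76.7 to 80.7%, 71.1 to 77.8% and 56.9 to 69.0%. In all 3 WT and no Id1tg list 3131 regions were called, and 777 in all 3 Id1tg and no WT list. Lists of equal length gave 1821 and 1506, and leaving out Id1tg 1 raised the numbers to 6601 and 870. Without Id1tg 2 the numbers were 3215 and 1282, and without Id1tg 3 they were 3189 and 1491. Leaving out a list relaxes the condition, so these counts can only rise or stay the same. Gene bodies held 60.5% of the WT-only regions, 46.1% of the Id1tg-only regions and 58.3% of those called in all 6.

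The WT-only regions of highest enrichment lay 23268 bp from Ccnl1, a cyclin of splicing (chromosome 3, 65922447 to 65923153, 12.1 to 15.1-fold), inside Anxa5, the annexin V gene (chromosome 3, 36467556 to 36468018, 12.0 to 13.4-fold), 157892 bp from the nearest protein-coding gene (chromosome 5, 75416723 to 75417464, 11.8 to 14.4-fold) and 96815 bp from the collagen gene Col12a1 (chromosome 9, 79501912 to 79502659, 11.3 to 13.3-fold). The Id1tg-only regions of highest enrichment lay 187850 bp from the nearest protein-coding gene (chromosome 10, 118633433 to 118633979, 13.0 to 16.0-fold), inside Fstl5 at 2 sites (chromosome 3, 76094324 to 76095083, 12.6 to 13.8-fold, and 76268292 to 76268907, 10.4 to 11.4-fold) and inside Il1r1, the IL-1 receptor gene (chromosome 1, 40315388 to 40315850, 10.1 to 14.0-fold).

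**Figure D3:**
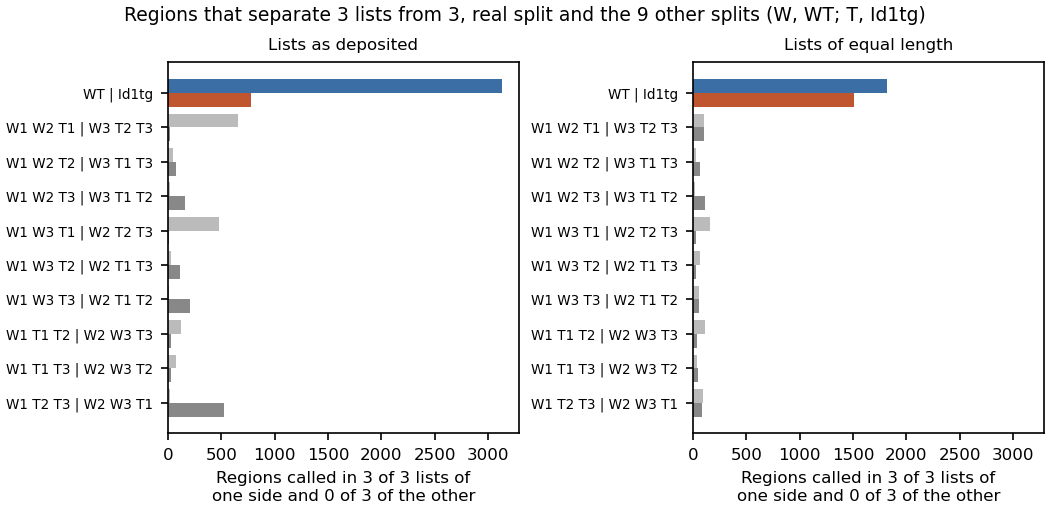
Regions called in all 3 lists of 1 side and none of the other (x axis, count) for the real split of the 6 lists (blue, WT; orange, Id1tg) and the 9 other splits (light and dark grey for the sides before and after the bar in each label), with lists as deposited (left) and of equal length (right). The real split gave 3131 and 777 regions, and 1821 and 1506 at equal length.

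Region sets defined in the first set were then read in the WT and Id1tg lists. Of the 1849 regions of ILC2 HDM absent from ILC2 PBS, 88.1% ± 0.797 were called in WT and 78.8% ± 4.98 in Id1tg (SD, n = 3, exact permutation p = 0.1, the smallest possible). At equal length the shares were 80.3% ± 3.74 and 75.1% ± 0.143 (n = 3, exact permutation p = 0.1). Regions of Th2 HDM absent from CD4 T PBS were called at 94.0% ± 0.409 and 86.3% ± 3.78 (n = 3, exact permutation p = 0.1), and 88.0% ± 3.4 and 83.9% ± 0.590 at equal length (exact permutation p = 0.2). Regions open in CD4 T PBS and not in Th2 HDM went the other way, with 81.4% ± 0.440 in WT and 84.7% ± 4.81 in Id1tg (n = 3, exact permutation p = 0.4) and 71.6% ± 3.4 and 81.9% ± 1.39 at equal length (exact permutation p = 0.1). Regions open in CD4 T PBS and not in ILC2 PBS had 71.7% ± 0.462 and 76.6% ± 7.61 (n = 3, exact permutation p = 0.4), and 57.2% ± 4.74 and 72.4% ± 2.30 at equal length (exact permutation p = 0.1). With lists as deposited, the differences of these CD4 T sets, 3.33 and 4.91 percentage points, were 0.771 and 0.810 without Id1tg 1 and 5.54 and 8.32 without Id1tg 3. Divided by the share of all regions called in the list, the 2 CD4 T sets had 0.890 ± 0.00399 and 0.784 ± 0.00429 in WT and 0.948 ± 0.0260 and 0.857 ± 0.0593 in Id1tg (n = 3, exact permutation p = 0.1 and groups apart for both). Without Id1tg 1 the difference of the second fell from 0.0731 to 0.0421.

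Regions of ILC2 HDM that Th2 HDM lacked were called at 93.0% ± 0.291 in WT and 87.7% ± 2.86 in Id1tg, and the Th2 HDM regions that ILC2 HDM lacked at 89.5% ± 0.749 and 80.2% ± 5.24 (n = 3, exact permutation p = 0.1 for both, and 0.4 for both at equal length). At equal length the differences were -2.24 and -2.53 percentage points, -3.51 and -5.30 without WT 2 (groups apart), -1.42 and -0.845 without WT 3, and the latter -1.46 without WT 1. Regions of ILC2 PBS lost with HDM had 85.0% ± 0.799 and 81.2% ± 3.90 (n = 3, exact permutation p = 0.3), and regions of ILC2 PBS absent from CD4 T PBS 89.0% ± 0.378 and 85.2% ± 3.28 (exact permutation p = 0.2). In both sets the Id1tg share was the higher at equal length, by 2.52 and 0.876 percentage points, but by 0.129 and -0.886 without WT 2, the list that stood apart. The differences with lists as deposited, -3.77 and -3.84, were -2.18 and -2.52 without Id1tg 3, and the former was -5.95 without Id1tg 1. The sets from Th2 HDM and CD4 T PBS (2 of 8) were not in the plan. Over the 8 sets, the Benjamini-Hochberg adjusted p was 0.2 or higher with lists as deposited and 0.114 or higher after the division. The other 6 sets were then lower in Id1tg, with differences of -0.0815 to -0.0191. Groups were apart for 5 of them, but not for regions of ILC2 PBS lost with HDM.

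**Figure D4:**
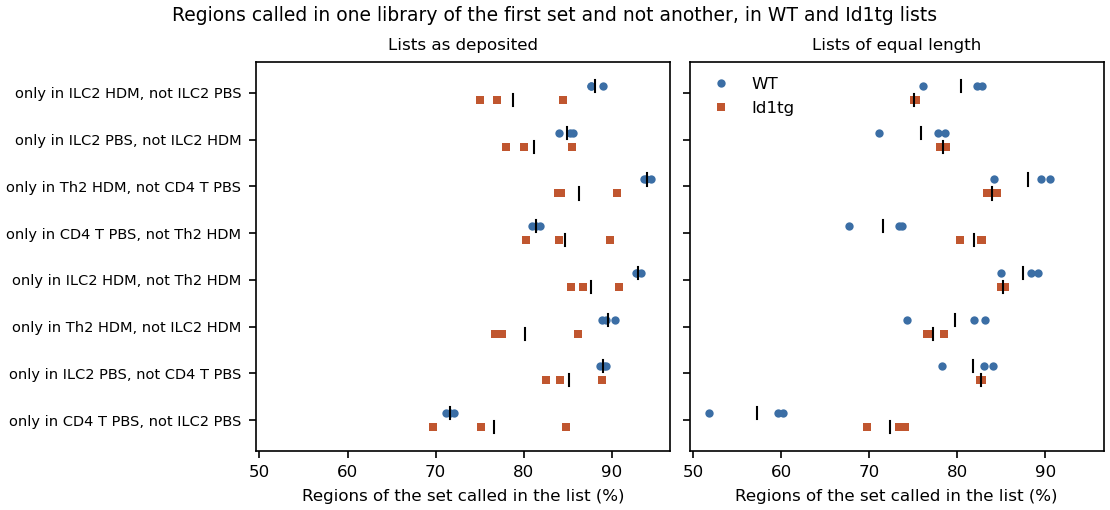
Share of each region set of the first set that was called in each WT (blue circles) and Id1tg (orange squares) list (x axis, percent), with lists as deposited (left) and of equal length (right); vertical bars are group means of 3 lists. Regions of CD4 T PBS absent from ILC2 PBS were called at 57.2% in WT and 72.4% in Id1tg with lists of equal length.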

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

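The tests on list length for the regions of WT and for the CD4 T cell regions, on a chromosomal segment and on other splits of the samples, and the division for regions of 2 lists together, were chosen only after the result was seen.

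ILC2 identity genes had a mean log2 ratio of called regions, HDM over PBS, of -0.20 in ILC2s and 0.50 in T cells. Antigen presentation and costimulation genes had -0.66 in ILC2s and 0.76 in T cells. These drew attention because both lists moved one way in ILC2s and the other way in T cells, each mean in the outer 5% of random lists. The mean was not the planned statistic: the medians lay at percentiles 2.45 and 59.2 for ILC2 identity and 49.0 and 50.9 for antigen presentation. The difference was not tested, since each side rests on 1 library, and the T cell comparison also changes the sorted population.

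More regions were called in all WT and no Id1tg lists (3131) than the reverse (777). With lists of equal length the ratio fell from 4.03 to 1.21, so list length is a candidate explanation of most of the excess. Equal length draws the numbers together whatever the cause, without fixing them (164 against 28 for WT 1, WT 3 and Id1tg 1 against the others). The fall therefore cannot tell list length from a loss of open sites in Id1tg. Without Id1tg 3 the ratio at equal length was 0.952. With 10 splits of the 6 samples no share below 0.1 is possible. The real split gave 3908 such regions and the highest other split 669, and 1 of the 10 splits, the real one, reached that count. For genes the real split gave 927 calls against 0 in the highest other split (2434 against 196 to 881 at an unadjusted p below 0.05, limma), again 1 of 10. With lists of equal length the real split gave 810 gene calls and the others 11 to 42. Each other split mixes the genotypes, so a genotype difference would lower its counts, and they are not null values.

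Id1tg-only regions lay far from genes more often than WT-only regions or those called in all 6 lists. No protein-coding gene was found within 100 kb for 19.6% of them (95% Wilson interval 16.9 to 22.5), against 6.77% of WT-only regions and 3.89% of those called in all 6 lists (13.9% against 5.77% with lists of equal length). List length or the quality of single libraries would give such shares in other splits too. The highest of the 7 other sets of at least 100 regions, that of WT 2, Id1tg 1 and Id1tg 2, had 10%. All 7 hold Id1tg 1, and none holds both Id1tg 2 and Id1tg 3. At equal length the set of WT 3, Id1tg 2 and Id1tg 3 (103 regions) had 2.91%. Every other split mixes the genotypes, so a quality shared by the 3 Id1tg libraries could not appear there. Of all summits, 5.60%, 5.52% and 5.93% had no gene within 100 kb in Id1tg 1 to 3. In WT 1 to 3 the shares were 4.77%, 4.49% and 4.69%. A single segment linked to the transgene would gather the Id1tg-only regions, but the fullest 5 Mb window (chromosome 3, 75 to 80 Mb) held 1.67%. A library quality shared by the Id1tg lists, genotype and GC content stay open, the last not tested because it needs the genome sequence.

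Regions open in CD4 T PBS and not in ILC2 PBS had a higher share called in Id1tg, by 4.91 percentage points with lists as deposited, where Id1tg 3 (69.8%) lay below every WT list, and by 15.2 with lists of equal length (shortening took 14.5 points from WT and 4.20 from Id1tg). List length as the whole cause is argued against: the Id1tg lists were on average the shorter, and after division by the share of all regions called in the list every Id1tg value lay above every WT value, by 0.0731 on average (0.0421 without Id1tg 1), while under both corrections regions of ILC2 HDM absent from ILC2 PBS were lower in Id1tg (-5.23 points and -0.0806, groups apart). T cells in the Id1tg sorts stay open, although the gate excluded cells with CD3 and with CD5 or TCRβ: regions open in both T cell lists and neither ILC2 list (221) differed by 9.05 points at equal length, but by -1.36 with lists as deposited and 0.00836 after the division (groups overlapping in both). T cell genes went both ways, with Cd2, Themis, Sh2d1a, Prkcq and the naive T cell genes Dapl1, Sell, Satb1 and S1pr1 higher, Bcl11b, which ILC2s also use, and Skap1 lower, and Cd3e at 2, 2 and 2 regions in WT and 3, 1 and 1 in Id1tg. A less HDM-exposed state stays open too, with regions open in both PBS lists and neither HDM list (466) differing by 3.58 points at equal length, -0.572 with lists as deposited and 0.0205 after the division (groups overlapping in the last 2), as does genotype itself.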

How the results depend on the processing

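Equal length with each sample left out, equal length with an estimated correlation, summit windows for genes, and gene assignment, pseudocount and filters for gene lists were chosen after the data were seen. Of 325 values of the main results, 255 kept their direction and side of the threshold or stayed within 1.5 times, and 70 did not: 26 counts moved by more than 1.5 times, 26 calls were lost, 5 were gained and 13 values turned. For peaks per list and region sets the exact p cannot fall below 0.1, so their values could only keep or turn direction. The replicate block leaves these values unchanged by construction. The 255 therefore overstates stability, and the number of peaks per list kept its direction under every alternative. For 57 named genes, 756 of 891 values kept direction and side, 83 lost and 38 gained a call and 14 turned. Unless stated, the cause was not tested. Motif results were not run. Counting overlapping peaks as deposited changed nothing, as none overlapped.

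Regions of WT only were 1821 at equal length (1960 to 2558 with a sample left out) and 3189 to 6601 with a sample left out of the full lists; those of Id1tg only were 1506 (1651 to 2360; 1820, 1651 and 1932 without WT 1 to 3 and 2360, 1895 and 2058 without Id1tg 1 to 3) and 870 to 1491. WT only at equal length were 1986 without Id1tg 2 and 1960 without Id1tg 3. With a sample left out fewer lists must meet the condition, so region counts can only rise or stay the same. Genes higher in Id1tg were 64 without division, 705 with the replicate block and 262 to 5021 with a sample left out, and genes lower were 734 with the block and 337 to 894.

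Adjusted p of camera with an estimated correlation was 0.242 (antigen presentation), 0.313 (type 2), 0.313 (STAT5), 0.502 (NF-kappaB) and 0.384 (naive T), and with equal length in addition 0.313, 0.545, 0.699, 0.699 and 0.313. Without division it was 0.0996 (type 2), 0.0996 (NF-kappaB) and 0.123 (naive T), at equal length 0.0740 (STAT5), and with the block 0.0908 (NF-kappaB). By gene body it was 0.134 (STAT5), 0.263 (naive T) and 0.0209 (ILC2 identity), within 20 kb 0.259 (naive T) and 0.0438 (ILC2 identity), at a mean of at least 2 regions 0.0634 (STAT5) and 0.260 (NF-kappaB), and with a pseudocount of 1 0.0378 (ILC2 identity). With a sample left out it ranged from 0.0113 to 0.0747 (STAT5), 0.0295 to 0.124 (NF-kappaB), 0.00022 to 0.778 (naive T), 0.0157 to 0.521 (ILC2 identity), 1.4e-06 to 0.00506 (type 2) and 3.5e-05 to 0.00322 (antigen presentation).

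Region sets turned at equal length for ILC2 PBS lost with HDM (2.52; 3.51, 0.129 and 3.93 without WT 1 to 3, 2.51, 2.36 and 2.69 without Id1tg 1 to 3) and ILC2 PBS absent from CD4 T PBS (0.876; 1.51, -0.886 and 2.01, and 0.935, 0.789 and 0.906). Between single libraries, 50% reciprocal overlap gave 2913 (ILC2 HDM against PBS), 2132 (Th2 against ILC2 HDM) and 3176 (CD4 T against ILC2 PBS) peaks of 1 list only, and equal length, which by construction removes peaks of the longer list, 2191 (ILC2 PBS against HDM), 1960 and 1929 (ILC2 against Th2 HDM) and 2722 (ILC2 against CD4 T PBS). Named genes that turned (log2) were Bach2 at the stricter q (0.00742; -0.127 to 0.0242 with a sample left out), Jun (0.14 at equal length, 0.17 at the stricter q), Sell (-0.0196) and Tcf12 (0.51) at equal length, Tcf12 with summit windows (0.0277), and by gene body Ccl1, Csf2 and Myc (0.19 each), Id2 (0.35, also 0.35 within 20 kb) and Tnfsf4 (0.10). The lists hold no depth; simulated changes of 2-fold were recovered in 24.6% of genes.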

Other observations

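The genes named here, the region sets of both HDM lists and of CD4 T PBS alone, and the shares per chromosome were chosen only after the results were seen, while the tests per gene and per list were planned.

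T lineage development genes (23 tested) did not pass as a list between WT and Id1tg ILC2s (limma camera adjusted p = 0.691, median -0.05 relative to all genes, mean log2 change 0.39), yet 8 rose and 2 fell, and 8 and 4 when adjusted over the list alone. Erg, a transcription factor of early T cell progenitors and of endothelium, had 1, 0 and 1 called regions in WT and 5, 4 and 3 in Id1tg (limma adjusted p = 0.000824), and the endothelial and stromal markers Kdr, Sox17 and Pdgfrb also rose while Tbx4 fell. Dntt, which adds nucleotides to rearranging antigen receptor genes, had 2, 2 and 2 against 5, 4 and 4 (0.00148), and the Notch target Dtx1 1, 1 and 2 against 5, 3 and 3 (0.00168). Sox4 and Bcl11a, both factors of lymphoid progenitors, had 2, 2 and 2 against 6, 6 and 4 (0.000449) and 4, 4 and 4 (0.00446). Satb1, Sox13 and Cd1d1 were the others that rose. Bcl11b fell, as did Ets1, a factor of mature lymphocytes, from 29, 39 and 27 regions to 25, 12 and 11 (limma adjusted p = 0.00662). At equal length Erg, Dntt and Satb1 passed, and Bcl11a, Cd1d1, Sox4, Dtx1, Bcl11b and Ets1 kept their direction without passing, and Sox13 could not be tested.

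Regions open in both HDM lists and neither PBS list of the first set (247) were called at 94.2% ± 2.70 in WT and 85.6% ± 2.00 in Id1tg with lists of equal length (SD, n = 3, exact permutation p = 0.1). Regions open in CD4 T PBS alone of the 4 single libraries (1520) were called at 46.8% ± 5.02 in WT and 65.6% ± 2.75 in Id1tg (n = 3, exact permutation p = 0.1), and at 63.6% ± 0.728 and 70.7% ± 9.18 with lists as deposited (n = 3, exact permutation p = 0.4).

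Id1tg-only regions were unevenly spread over chromosomes. Relative to the share of all regions, chromosome 18 held 1.98 times and chromosome 3 1.77 times as many, and chromosome 11 0.262 times.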
